A study of Homo sapiens with 6 samples.

How the data were processed

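Total RNA of WM-266.4 melanoma cells was profiled on Affymetrix HG-U133 Plus 2 arrays, which carry several short oligonucleotide probes per transcript summarised as a probe set. Per the labels' protocols, cells were seeded 24 h before transfection, received 200 pmol of siRNA with Oligofectamine in medium without serum, and were harvested 72 h later. Per the series' design text, equal amounts of RNA from 3 independent extractions were mixed for each group, and the biotin-labelled target of each mixture was hybridised to 2 arrays. The groups are siPIR (siRNA against PIR), siCTR (non-targeting siRNA) and NO (reagent alone), with 2 arrays each. The array duplicates are technical, so n is 1 RNA pool per group, and arrays of a pool were averaged before any comparison. The number of pools and arrays limits the precision, and no interval for the conditions can be had from a pair of pools.

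The values deposited by the authors are probe set intensity on a linear scale, 1 per array and probe set. Per the submitters' processing notes they were made with GCOS, the Affymetrix array software; its version and settings are not given in the sources used here. On each array the mean after leaving out the lowest and highest 2% of probe sets was 500 to within rounding, the pattern that global scaling to a target of 500 leaves. Such scaling removes differences in total signal between arrays, so a change of total RNA per cell would not be seen. No detection calls were used. All 6 columns were matched to their samples, and 0 columns were left unmatched.

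Values were transformed as log2(value + 5.4), the pseudocount being the 10th percentile of all values on the 6 arrays. All fold changes are on this scale, which understates differences of dim genes. Of 54675 probe sets, 41097 were annotated with 1 gene, 1801 with several and 11777 were not listed in the platform annotation used, among them the 62 control probe sets. Symbols were matched through Entrez identifiers to a RefSeq gene table of GRCh38.p14; 99.9% matched and 0 changed. No coordinates are given, as no genome build is stated for the array values. Each of 19775 genes was represented by the probe set with the highest mean among those annotated with it alone. A gene was measured when the mean of at least 1 pool was above 70.2, the median of all values, which left 13053 genes. Of these, 8271 with a pool mean above 458.4 (the 75th percentile) are called bright and 4782 dim. Some members of the gene lists have no probe set annotated with that gene alone and were not analysed here. Genes represented by a probe set marked as shared between genes (suffix _x_at) are called uncertain.

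Between 2 pools a gene was called when the log2 difference of the pool means was at least 1 in size (2-fold) and both arrays of a pool lay beyond both arrays of the other. This is a rule of size and hybridisation error, not a test of the conditions. The range given after a difference is over the 4 pairs of arrays. Benchmarks of hybridisation error came from 100 simulations of pools without any difference, with array noise drawn from duplicate differences within 50 bins of mean signal, a step added after the data were seen. These simulations leave out variation between separately prepared pools, so they are not a benchmark for differences between cultures. They also take the measured genes as given and do not apply the filter again. The fit across samples used limma (lmFit and eBayes) on the 3 pool means, siPIR against siCTR and NO, with 1 residual degree of freedom and Benjamini-Hochberg adjustment over all measured genes at 0.05. List counts from limma were also adjusted over the list alone.

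For 20 gene lists, the median log2 difference of the measured members was placed as a percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. A list was called shifted outside the 2.5 to 97.5 percentile range, as a description of these pools, and lists with fewer than 5 measured members received no percentile. The lists were DNA replication and G1/S, G2/M and mitosis, senescence-associated regulators, p53 targets, NF-kB targets and inflammatory factors, pigmentation and melanocyte lineage, epithelial-mesenchymal and migration, and interferon-stimulated genes. Further lists were NRF2 targets, MAPK pathway output, unfolded protein and amino acid stress response, cholesterol synthesis and uptake, hypoxia and glycolysis, lysosome and autophagy, NFI and BCL3 partners of pirin, and heat shock genes. Markers of fibroblasts, keratinocytes, leukocytes and endothelial cells made up the remaining 4 lists. CDKN1A is in both the senescence and p53 lists, and SESN2 in both the p53 and unfolded protein lists.

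Genes were named by a fixed rule. PIR came first. Against both controls, the 12 higher and 12 lower called genes with the largest smaller difference were taken. The 5 higher and 5 lower with the largest difference were taken against siCTR and against NO, and 8 each between siCTR and NO. Up to 4 members per list with the largest difference from siCTR (between the controls, from NO) were named, as were genes past the limma threshold. List members outside that rule were named where they passed or missed a call, and bright genes were ranked again, after their values were seen.

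The groups, the size rule, the limma design, the lists, the naming rule and the alternatives were set before the data were examined, except where stated. The alternatives changed the pseudocount to 0.5 or 4 times its value, removed the filter or raised it to the 75th percentile, applied quantile normalisation or median centring, averaged all probe sets of a gene or left out those with the suffixes _x_at and _s_at, required 1.5-fold or 3-fold, paired arrays by number, ran limma on the 6 arrays or with a variance trend, and left out each array in turn. The probe set with the highest mean was chosen anew under each of these, so that another probe set may represent a gene.

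The scripts were tested on simulated data with array noise of the same kind, in which 200 of 13053 genes were changed. The rule for siPIR against siCTR recovered 93.1% of 87 genes changed by 1.5 on the log2 scale and 99.1% of 113 changed by 2, and called 246 of 12853 unchanged genes. Against both controls it recovered 88.5% and 99.1% and called 93 unchanged genes. The limma fit on 3 pools recovered 0% at either size, and with the variance trend 86.2% and 91.2%, with 45 unchanged genes called. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.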

Results

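Gene expression was measured in WM-266.4, a cell line from a metastatic human melanoma, after knock-down of PIR. PIR encodes pirin, an iron-binding nuclear protein of the cupin family known as a partner of NFI transcription factors and of the NF-kB co-regulator BCL3. Cells received a pool of 4 siRNA duplexes against PIR (siPIR), a pool of 4 non-targeting duplexes (siCTR), or the lipid reagent without any oligonucleotide (NO), and were collected 72 h later. RNA of 3 separate extractions was combined for each group, and the labelled target made from that mixture was placed on 2 Affymetrix HG-U133 Plus 2 arrays. Each group is therefore 1 RNA pool, its 2 arrays are repeat hybridisations counted as 1 sample, and differences between pools have no biological replicate behind them. The spread between the 2 arrays measures hybridisation error only, and the number of arrays limits the precision.

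The 6 arrays held signals for 54675 probe sets each, with medians of 67.0 and 71.3 (siPIR), 70.9 and 64.2 (siCTR), and 72.9 and 74.8 (NO). Among bright genes, defined by a highest pool mean above 458.4 signal units (the other measured genes are called dim), duplicate arrays correlated across genes at r of 0.992, 0.993 and 0.994 for siPIR, siCTR and NO. An siPIR array correlated with arrays of the other pools at 0.941 at most, and siCTR with NO arrays at 0.987 at most. Over all measured genes, siCTR replicate 2 correlated with NO replicate 1 at 0.9749 and with its own duplicate at 0.9746. These correlations are across genes, which are not independent replicates. The ratio of 3' to 5' signal of ACTB, a measure of RNA integrity, was 1.13 on each siPIR array and 1.23 to 1.26 on the siCTR and NO arrays. That of GAPDH was 0.908 and 0.904 for siPIR, 0.919 and 0.948 for siCTR, and 0.972 and 0.961 for NO.

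PIR itself was examined first, since it checks the labels. Its signal (1 measured probe set) was 392 and 382 on the siPIR arrays, 13544 and 13180 on the siCTR arrays, and 13990 and 14153 on the NO arrays. The log2 difference was -5.09 against siCTR (-5.13 to -5.05 over the 4 pairs of arrays), a 34.1-fold lower level, and -5.17 against NO (-5.19 to -5.14), a 35.9-fold lower level. No other measured gene had as large a fall in either comparison. Between siCTR and NO, PIR differed by -0.07 (-0.10 to -0.05).

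The comparison of the siPIR pool with both control pools asks which transcripts differ from the non-targeting siRNA and from the reagent alone. It does not remove genes that also differ between the controls. Most measured genes of the mitosis and replication lists and 5 of 16 of the cholesterol list were called lower in the siPIR pool. The glucose transporter SLC2A3, the collagenase MMP1, the integrin ITGA5 and the histone gene H2AC6 were among those higher. Of these, SLC2A3 (0.97 to 0.98 with an array left out) and ITGA5 (0.89) were also higher in siCTR than in NO on the log2 scale. MMP1 (0.20) and H2AC6 (-0.08) differed little between the controls. A gene was called when its log2 difference was at least 1 in size and both arrays of the siPIR pool lay beyond both arrays of the control pool, against siCTR and against NO alike. Of 13053 measured genes, 192 were higher and 418 were lower by this rule, and of the 8271 bright genes 75 were higher and 281 lower. The count of higher genes was 358 without siPIR replicate 1 and 300 without siPIR replicate 2. A lone array cannot overlap its partner, which relaxes the rule, but how much of the rise this gives was not tested. Pools simulated without any difference, from the spread between duplicate arrays, gave a median of 34 higher and 34 lower genes, and 0 in each direction among the bright genes. The simulations hold hybridisation error only, so these counts leave out variation between separately prepared pools. For 1 pair of pools, chance alone separates 2 arrays from 2 others in 33.3% of genes, in either direction. A call against both controls asks for more, so this share is not its benchmark.

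Among the 12 higher genes with the strongest difference, 3 were bright. H2AC6, a histone H2A gene, had log2 differences of 2.76 against siCTR (2.55 to 2.97 over array pairs) and 2.68 against NO (2.38 to 2.98). SLC2A3, a glucose transporter, was higher by 2.22 (2.21 to 2.23) and 3.19 (3.18 to 3.21), with a mean signal of 3797 in siPIR, 812 in siCTR and 410 in NO. With an array left out, when another probe set may represent SLC2A3, its differences ranged from 1.63 to 2.22 and from 2.26 to 3.20. ANGPTL4, a secreted inhibitor of lipoprotein lipase, was higher by 2.24 and 2.81. The other 9, which are dim (TCAF2, DNAAF3-AS1, MYOM2, ELAPOR1, CCDC7, CLBA1, GPR26, CYP11B2 and EBLN2) had signals near the lower limit of the measured range. Of these, TCAF2 was the strongest, at 2.69 and 2.63, with a mean siPIR signal of 125 against 15.5 in siCTR. GPR26 and MYOM2 were the least even, with pairs of arrays from 0.22 to 3.82 and from 0.66 to 3.69 against siCTR, and with an array left out both fell below 2-fold (0.40 and 0.81). At 4 times the pseudocount the 9 dim genes were higher by 1.34 to 2.00 against siCTR, and the 3 bright ones by 2.19 to 2.57.

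Among the 12 lower genes, PIR led and 6 were bright. SHCBP1, which acts in cytokinesis, was lower by a log2 difference of -2.83 against each control (-2.97 to -2.70 against siCTR). DEPDC1, a gene of mitotic cells, differed by -2.65 and -2.50, LDLRAD3 by -2.46 and -2.51, and COMMD1, a regulator of copper handling and NF-kB, by -2.43 and -2.35. AP3S1, a subunit of the AP-3 vesicle adaptor, differed by -2.30 and -2.31, with signals of 1503 in siPIR and 7390 in siCTR. The 6 dim ones were LIN9, a subunit of a complex that controls mitotic genes (-2.91 and -3.13), SPOCK2 (-2.70 and -3.15), ID3, an inhibitor of helix-loop-helix transcription factors (-2.55 and -2.61), SLC4A8 (-2.42 and -2.87), ARHGAP11A (-2.40 and -2.58) and EVPLL (-2.35 and -2.55). The siPIR signals of ARHGAP11A were 67.9 and 6.2, and its differences ranged from -3.73 to -1.07 and from -3.91 to -1.25 when an array was left out. The lowest pool means of these 6 were 6.65 (SPOCK2) to 37.1 signal units, so the size and order of their differences depend on the pseudocount of 5.4. At 4 times the pseudocount they were -2.41 to -1.56 against siCTR and -2.62 to -1.72 against NO, with SPOCK2 at -1.70 and -2.09. LIN9 is uncertain because its only probe set can bind transcripts of several genes.

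Because most of the strongest higher genes were dim, the ranking was repeated among the bright genes, a choice made after the values were seen. It added MMP1 (1.96 and 2.16), ITGA5, the alpha chain of a fibronectin receptor (1.66 and 2.55), GPR158 (1.85 and 1.73), H2BC21, a histone H2B gene (1.97 and 1.61), SLC12A8 (1.63 and 1.88), DNAI3 (2.06 and 1.58), SERPIND1 (1.53 and 1.79), PCDHB14 (1.46 and 1.52) and SUGCT-AS1 (1.84 and 1.46). On the lower side it added UXS1, which makes UDP-xylose (-2.29 and -2.38), DEPDC1B (-2.27 and -2.57), RAVER2 (-2.24 and -2.38), the spindle checkpoint kinase TTK (-2.20 and -2.20), B4GALT4 (-2.25 and -2.15) and the condensin subunit NCAPH (-2.31 and -2.14).

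**Figure D1:**
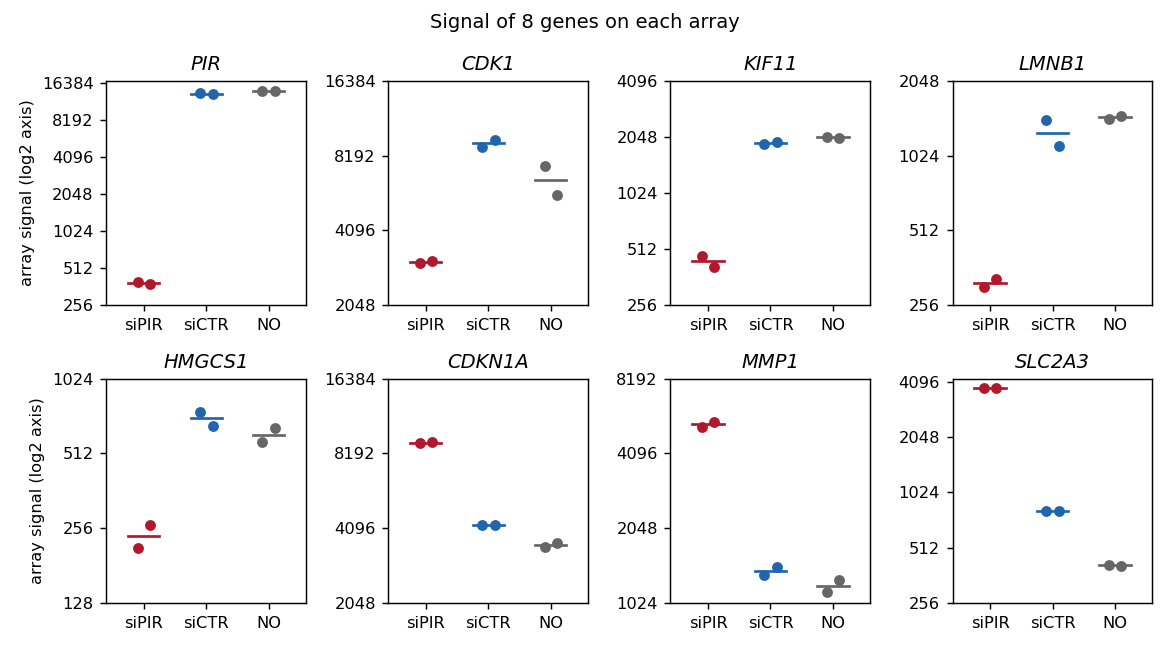
Array signal (log2 axis) of 8 genes in the siPIR, siCTR and NO pools. Points are the 2 arrays of each pool and lines their mean. PIR lies at 392 and 382 in siPIR and at 13180 to 14153 in the controls, and CDK1, KIF11, LMNB1 and HMGCS1 are lower, and CDKN1A, MMP1 and SLC2A3 higher, on both siPIR arrays than on all 4 control arrays.

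Genes of the cell cycle were lower in the siPIR pool nearly as a block. Of 30 measured G2/M and mitosis genes, 28 were called lower than both controls and 0 higher, and the list's median log2 difference was -1.69 against siCTR and -1.62 against NO, below all 10000 random lists of matched expression. CDC25C, the phosphatase that activates CDK1, was lower by -2.27 and -2.16 (dim), TTK by -2.20 and -2.20, the spindle motor KIF11 by -2.11 and -2.20, and the checkpoint kinase BUB1 by -2.10 and -1.96. The 2 not called were AURKA (-1.24 and -0.98) and PTTG1 (-0.72 and -0.61, uncertain probe set). Of 29 measured DNA replication and G1/S genes, 22 were called lower than both controls, with medians of -1.37 and -1.36, again below all random lists. Thymidine kinase TK1 was lower by -1.98 and -1.82, the licensing factor CDT1 by -1.95 and -1.93, the helicase subunit GINS2 by -1.90 and -1.82, and the clamp loader subunit RFC3 by -1.86 and -1.91. Other probe sets of CDT1, GINS2 and RFC3 gave differences from siCTR as small as -0.71, -0.91 and -0.52, and CDT1 rests on a probe set that may bind other transcripts. In both lists every measured member had a negative difference from each control. The 3' to 5' ratios of ACTB and GAPDH were lowest in the same pool, so its RNA showed no excess of 3' signal over the controls.

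The senescence-associated regulators held calls in both directions. The list does not say which direction of a member belongs to senescence, so its median does not test for that state. Of 15 measured, 4 were lower than both controls and 1 higher, and the median was -0.58 against siCTR (below all random lists) and -0.39 against NO (0.20 percentile). The lower ones were LMNB1, lamin B1 of the nuclear envelope (-1.99 and -2.20), the chromatin protein HMGB2 (-1.80 and -1.52), the cyclin-dependent kinase inhibitor CDKN1C (-1.68 and -1.36) and the histone methyltransferase EZH2 (-1.28 and -1.35). Another probe set of CDKN1C differed from siCTR by only -0.34. The higher one was CDKN1A, which encodes the kinase inhibitor p21 and is also in the p53 list (1.10 and 1.37, with 1.10 to 1.11 over array pairs against siCTR).

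Of 20 measured p53 targets, 3 were called higher than both controls and 0 lower, 18 had a positive difference from each control, and the median difference was 0.52 against siCTR and 0.68 against NO, above all random lists in each case. TP53INP1 was higher by 1.27 and 1.29, SESN2 by 1.14 and 1.70, and CDKN1A as given. The pro-apoptotic gene BAX differed by 0.84 and 0.91 and was not called.

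Of 17 measured NF-kB targets and inflammatory secreted factors, MMP1 was higher and SOD2, a mitochondrial superoxide dismutase, lower than both controls (-1.45 and -2.03, dim), although SOD2 was only -0.95 from siCTR with an array left out. The median was 0.60 against siCTR (99.99 percentile) and 0.40 against NO (99.4 percentile), and the first was 0.30, inside the random range, without _x_at and _s_at probe sets. The chemokine CCL2 was higher against siCTR (1.42) and not against NO (0.40), and TNFAIP3, an inhibitor of NF-kB signalling, differed by 0.83 and 0.87. Against NO alone, CXCL8 (1.35, uncertain probe set), ICAM1 (1.24) and CCL20 (1.07) were also called higher. The 8 measured NFI and BCL3 partners of pirin had medians of 0.11 and -0.12 (66.6 and 19.6 percentile), within the range of random lists. Among them NFKB2 differed by 0.69 and 0.69, NFIA by -0.69 and -1.04 (called lower against NO), NFIB by 0.32 against siCTR (-0.18 as the mean over probe sets) and NFKB1 by -0.30 and -0.24. NFIA was only -0.33 from NO with an array left out, when another probe set represented it.

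Of 16 measured genes of cholesterol synthesis and uptake, 5 were called lower than both controls and 0 higher, while 11 were not called, with medians of -0.61 against siCTR (below all random lists) and -0.50 against NO (0.010 percentile). The transcription factor SREBF2 was lower by -1.60 and -1.36, HMGCS1, an early enzyme of the pathway, by -1.56 and -1.34, ACAT2 by -1.26 and -1.04 (-0.95 from NO with an array left out), STARD4 by -1.23 and -1.09, and FDPS by -1.12 and -1.08. Another probe set of SREBF2 differed from siCTR by -0.14.

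Of 22 measured hypoxia and glycolysis genes, the neuronal enolase ENO2 was called higher than both controls (1.43 and 1.95), and the medians were 0.29 and 0.45, above all random lists. The angiogenic factor VEGFA differed by 0.79 and 1.19 (called against NO), the collagen prolyl hydroxylase P4HA1 by 0.74 and 0.73, and hexokinase HK2 by 0.83 and 0.48. The probe sets of HK2 disagreed in sign, from -0.41 to 0.83 against siCTR, and P4HA1 differed by -0.73 and -0.098 as the mean over its probe sets. Of 23 measured epithelial-mesenchymal and migration genes, 3 were higher than both controls, namely ITGA5, the urokinase receptor PLAUR (1.28 and 1.92) and the membrane protease MMP14 (1.07 and 1.38). The list's medians of 0.15 and 0.10 were within the range of random lists (93.8 and 65.8 percentile), and the first was above it without _x_at and _s_at probe sets (0.22) or without siCTR replicate 1 (0.18). CDH11 differed by -1.84 and -1.38 and was not called, as its arrays overlapped. Its direction is not settled, since without siPIR replicate 2 another probe set represented CDH11 and gave 1.98 and 0.68.

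Pigmentation genes did not move together. Of 21 measured pigmentation and melanocyte lineage genes, 0 were called against siCTR or against both controls, and the medians were 0.02 and 0.10 (49.96 and 66.7 percentile). TRPM1 differed by -0.77 and -1.67 and OCA2 by -0.69 and -1.42, both called lower against NO alone, while GPR143 differed by -0.44 and -0.27 and TYRP1, a melanin enzyme, by 0.40 and 0.22. Of 26 measured interferon-stimulated genes, OAS2 was higher than both controls (1.13 and 1.15, dim; 0.82 and 0.85 at the lowest with an array left out). IFIT1 (1.15) and IFI6 (1.04) were called higher against siCTR alone, and DDX60 (-0.85 and -1.42) and TLR3 (-0.58 and -1.13) lower against NO alone, and IFI6 (0.87) and TLR3 (-0.86) fell below 2-fold with an array left out. The medians were 0.36 (99.9 percentile) and 0.30 (99.1 percentile), and the second was inside the random range without either siPIR array (0.25 each).

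Of 20 measured NRF2 targets, 0 were called against both controls, with medians of 0.27 (99.3 percentile) and 0.26 (97.9 percentile). AKR1B10 was called higher against siCTR (1.76, from 1.004 to 2.52 with an array left out) but differed from NO by 0.30, EPHX1 differed by 0.75 and 0.81, OSGIN1 by 0.59 and 0.70, and AKR1C1 by 0.56 and 0.44 (uncertain probe set). The median against NO was inside the random range without either siPIR array or without NO replicate 1, at 0.21 to 0.26, and that against siCTR as the mean over probe sets (0.22). Of 21 measured lysosome and autophagy genes, 0 were called in either comparison, although the medians of 0.27 and 0.31 lay at the 99.9 and 99.6 percentiles. The median against siCTR was inside the random range as the mean over probe sets (0.19). NEU1 differed by 0.70 and 0.88, ATP6V0D1 by 0.45 and 0.24, MAP1LC3B by 0.40 and 0.30 and the protease CTSD by 0.39 and 0.55.

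Of 23 measured genes of the unfolded protein and amino acid stress response, SESN2 and PPP1R15A (1.02 and 1.09) were higher and the serine synthesis enzyme PHGDH lower (-1.17 and -1.10) than both controls, with medians of 0.07 and 0.21 (75.4 and 95.7 percentile). XBP1 differed by -0.90 and -1.003, called lower against NO alone, and with an array left out PPP1R15A (0.96 from siCTR) and XBP1 (-0.94 from NO) fell below 2-fold. Of 21 measured MAPK pathway output genes, 0 were called against both controls, with medians of 0.16 and 0.19 (94.8 and 92.3 percentile), the first above the random range with the filter at the 75th percentile (0.23). FOS differed by -0.89 and -1.19, JUN by 0.83 and 0.39 (uncertain probe set, -0.11 from NO as the mean over probe sets), MAFF by -0.76 and -0.67 and FOSL1 by 0.72 and 0.99. The 12 measured heat shock genes had medians of -0.04 and 0.02 (21.6 and 35.3 percentile), with HSPH1 at -0.94 and -1.06 (called lower against NO), HSPB8 at 0.74 and 0.60, CRYAB at 0.47 and 0.41 and HSPA6 at 0.32 and 0.60.

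Markers of other cell types were read beside these lists. Of 9 fibroblast markers 5 were measured and 0 called, with medians of 0.26 (87.3 percentile) and 0.71 (99.8 percentile). FAP differed by 0.92 and 0.99, COL1A2 by 0.64 and 0.91, LUM by -0.44 and -0.61 and POSTN by 0.26 and 0.42. As the mean over probe sets LUM (0.63 and 0.093) and POSTN (-0.23 and -0.068) had the opposite sign. COL1A2 had mean signals of 23050, 14790 and 12260 in siPIR, siCTR and NO. The fibroblast median against siCTR was above the random range without the filter (0.92) or without siPIR replicate 2 (0.67), and that against NO was inside it without the filter (0.42) or without NO replicate 2 (0.34). Of 8 keratinocyte markers 1 was measured (KRT10, -0.37 and -0.32), of 8 leukocyte markers 3 (CD14 at 0.88 and 1.64, ITGAM at -0.40 and -1.33, LCP1 at 0.31 and -0.24), and of 7 endothelial markers 2 (PECAM1 at 0.91 and -0.02, KDR at 0.10 and -0.59). CD14 was called higher and ITGAM lower against NO, both dim, and ITGAM was -0.94 with an array left out.

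**Figure D2:**
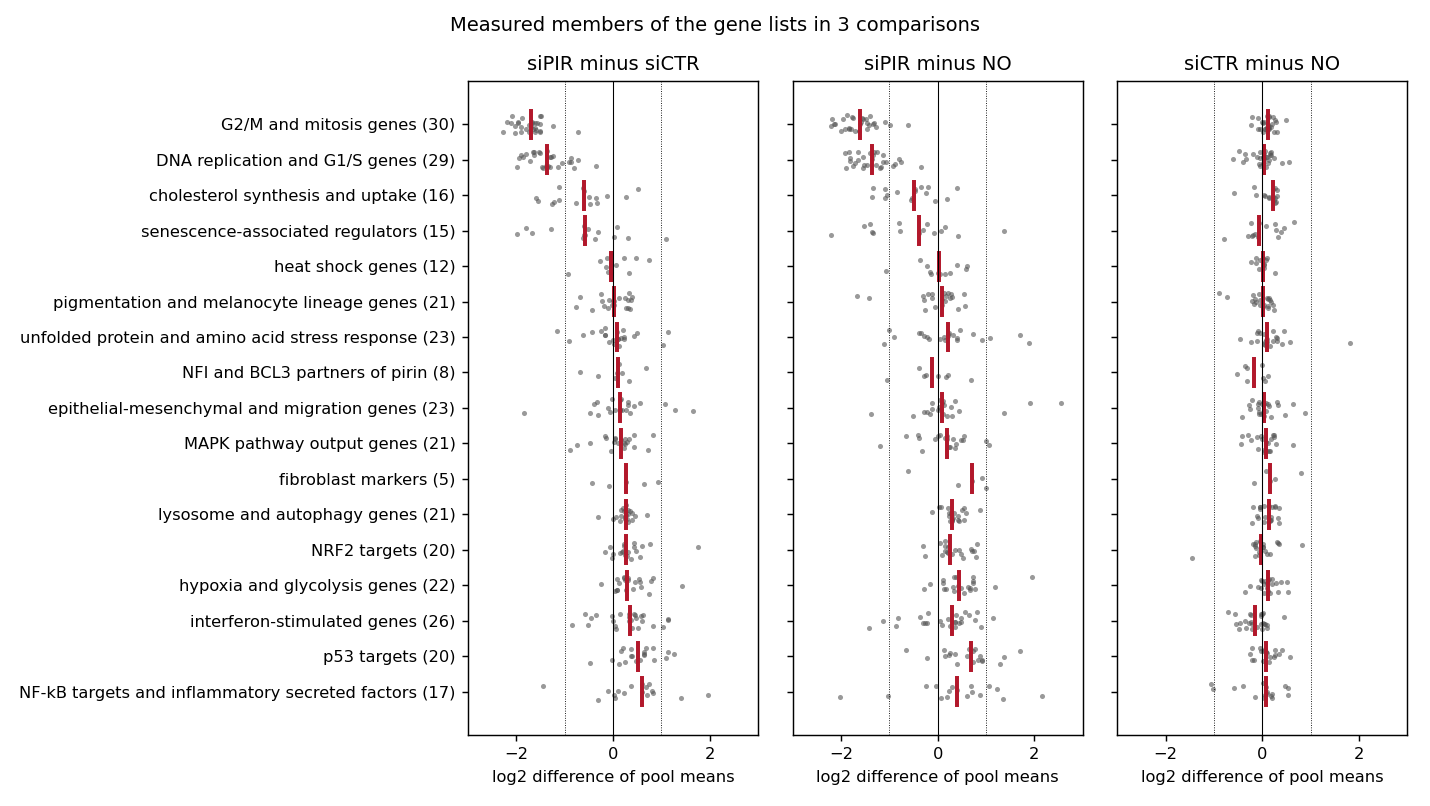
Log2 difference of pool means (horizontal axes) for each measured member (points) of the 17 gene lists with at least 5 measured members, in 3 comparisons, with the list median as a red line, the number of measured members in brackets, and dotted lines at -1 and 1. The mitosis and replication lists lie at medians of -1.69 and -1.37 for siPIR minus siCTR and at 0.11 and 0.03 for siCTR minus NO.

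Against siCTR alone, which asks what the PIR duplexes did beyond a non-targeting siRNA, 478 genes were higher and 550 lower, of which 110 and 331 were bright. The counts reached 784 higher without siPIR replicate 1 and 982 lower without siCTR replicate 2. Simulated unchanged pools gave a median of 122 higher and 121.5 lower, and of 0 in each direction among bright genes. The 5 higher genes named by the size of the difference were all dim, namely CCDC141 (4.29), the secreted glycoprotein STC1 (3.17), the interferon-induced antiviral gene RSAD2 (3.11), CAPS (3.06) and DGKB (2.87). Their mean siCTR signals were 1.6, 24.5, 5.65, 10.15 and 6, which but for that of STC1 are near or below the pseudocount of 5.4, so the size and order of these differences depend on it. At 4 times the pseudocount they ranged from 1.85 (DGKB) to 2.72 (CCDC141). STC1 ranged from 2.05 to 4.28 with an array left out. RSAD2 differed from NO by -0.04 and CAPS by 0.77. The direction of CAPS is not settled, as its probe sets ranged from -0.52 to 3.06 against siCTR, and without siPIR replicate 2 another probe set represented it and gave -1.28 from siCTR and -2.65 from NO. Next to PIR and LIN9, the lower genes named were ABI3BP (-3.28), TMEM63C (-3.05) and SDK2 (-2.88), at -2.09, -2.12 and -1.93 with 4 times the pseudocount, and TMEM63C differed from NO by 0.11.

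Against NO, which adds the effects of carrying an siRNA, 470 genes were higher and 705 lower, of which 177 and 353 were bright, where simulated unchanged pools gave a median of 122.5 and 124. The higher genes named were the transporter gene SLC6A17 (3.46, dim), SLC2A3, ANGPTL4, DNAAF3-AS1 (2.77) and SLAMF9 (2.68). At 4 times the pseudocount SLC6A17 was at 2.81, below SLC2A3 (3.15), and DNAAF3-AS1 at 1.98. SLC6A17 differed from siCTR by 0.79 and was itself higher in siCTR than in NO. Next to PIR, the lower genes named were SPOCK2, LIN9, SLC4A8 and the cell adhesion gene OPCML (-2.85), all dim. Their order also depends on the pseudocount, as at 4 times its value LIN9 was at -2.62, SPOCK2 at -2.09, SLC4A8 at -2.05 and OPCML at -1.86. The calls of both comparisons shared 192 higher and 418 lower genes, where independent lists would share 17.2 and 29.7, and simulated unchanged pools share 34 and 34. Both comparisons use the same siPIR arrays, so part of the excess may come from these shared arrays. Only 4 genes were called in opposite directions, 0 of them bright.

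The comparison of siCTR with NO, 1 pool each, asks what a non-targeting siRNA does beyond the reagent. Nearly all calls fell on dim genes. In total 130 genes were higher and 313 lower in siCTR, of which 2 and 3 were bright. Unchanged pools simulated for this pair gave medians of 124 higher and 123 lower, with at most 170 and 156. The excess of lower calls depends on the arrays, as the counts were 509 higher and 505 lower without siCTR replicate 2 and 246 and 596 without NO replicate 1. The 8 largest higher differences were in LBX1-AS1, TMEM63C, FCN2, SLC6A17, RBFOX1, BARX1, DLGAP1-AS6 and LINC02837 (2.27 to 3.30). The 8 largest lower ones were in RSAD2, YJEFN3 (uncertain probe set), LOC105371038, the opioid precursor PENK, C2CD4C, RASD1, PNMA3 and LYZL4 (-3.15 to -2.67). All 16 were dim, with the brightest pool mean between 72.3 and 276 signal units, and the lower of their siCTR and NO means was between 5.05 and 21.5. At 4 times the pseudocount they were 1.58 to 2.18 and -2.05 to -1.76. RBFOX1 was -0.10 as the mean over probe sets. With an array left out RBFOX1 ranged from 1.26 to 2.97, and C2CD4C from -3.63 to -1.77. The 5 bright calls, named after their values were seen, were DECR2 (1.20) and ST8SIA5 (1.01) on the higher side and PIK3C2B (-1.52), COX3 (-1.11, uncertain probe set) and BLZF1 (-1.10) on the lower.

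Most gene lists differed little between siCTR and NO. Of their members, 1 was called higher, CHAC1 (1.81), and 2 lower, AKR1B10 (-1.46) and CCL2 (-1.01), all dim. Each fell below 2-fold with an array left out, CHAC1 ranging from 0.71 to 2.92, AKR1B10 from -2.21 to -0.70 and CCL2 from -1.22 to -0.81. The mitosis list had a median of 0.11 (96.7 percentile, CDK1 at 0.49), above the random range as the mean over probe sets (0.12) or without _x_at and _s_at probe sets (0.13), and the replication list one of 0.03 (50.4 percentile, UNG at -0.60). Lists outside the 2.5 to 97.5 percentile range of random lists were cholesterol synthesis and uptake (0.22, 99.96 percentile, DHCR7 at 0.31), lysosome and autophagy genes (0.14, 98.8 percentile, MCOLN1 at 0.35), interferon-stimulated genes (-0.16, 0.25 percentile, OAS1 at -0.70) and the NFI and BCL3 partners (-0.16, 2.12 percentile, NFIX at -0.52). The cholesterol median was -0.016 as the mean over probe sets, the opposite sign, and 0.14, inside the random range, without _x_at and _s_at probe sets. The NFI and BCL3 median was 0.042 without NO replicate 1 and 0.058 as the mean over probe sets. It was inside the random range with the filter at the 75th percentile (-0.16) and without siCTR replicate 1 (-0.13) or NO replicate 2 (-0.12). The lysosome median was inside the random range without siCTR replicate 1 or either NO array (0.092 to 0.12), and the interferon median without NO replicate 2, as the mean over probe sets or without _x_at and _s_at probe sets (-0.11 each).

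Medians within the random range were found for the senescence (-0.06, 5.66 percentile, CDKN2A at -0.79, uncertain probe set), p53 (0.08, 83.7 percentile, SESN2 at 0.57), NF-kB (0.08, 88.1 percentile, IL1B at -1.06, from -2.52 to 0.40 with an array left out), pigmentation (0.02, 23.0 percentile, TRPM1 at -0.91), migration (0.03, 42.6 percentile, ITGA5 at 0.89) and NRF2 lists (-0.02, 17.3 percentile). The same held for the MAPK (0.07, 76.3 percentile, DUSP5 at 0.63), unfolded protein (0.09, 89.2 percentile), hypoxia (0.11, 96.3 percentile, BNIP3 at 0.54), heat shock (0.02, 33.5 percentile, HSPA6 at 0.27) and fibroblast lists (0.15, 91.5 percentile, COL1A1 at 0.80, uncertain probe set). The pigmentation median was -0.081, below the random range, as the mean over probe sets. The hypoxia median was above the random range with quantile normalisation (0.093), as the mean over probe sets (0.12), without _x_at and _s_at probe sets (0.17), without siCTR replicate 1 (0.15) and without NO replicate 2 (0.13). The median over all measured genes was 0.05 for siPIR minus siCTR, 0.03 for siPIR minus NO and 0.01 for siCTR minus NO.

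**Figure D3:**
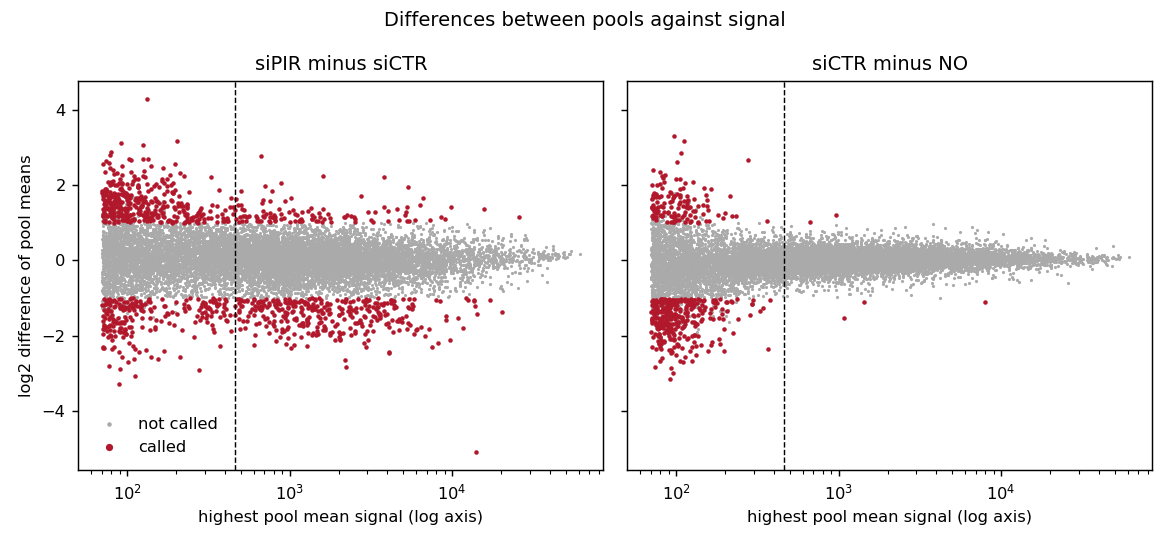
Log2 difference of pool means (vertical axis) against the highest pool mean signal (log axis) for 13053 measured genes, for siPIR minus siCTR and siCTR minus NO. Red points are called genes, and the dashed line at 458.4 separates dim from bright, with 441 bright calls in the siPIR comparison and 5 between the controls.

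The only fit with a degree of freedom left among samples set the siPIR pool against both control pools together. In limma on the 3 pool means, 0 of 13053 genes passed an adjusted p of 0.05. At an unadjusted p under 0.05 there were 1324 higher and 1428 lower genes, where 652.65 in all would be expected by chance. PIR had a log2 difference of -5.13 in this fit, and its adjusted p, the lowest of any gene, was shared with other genes. Genes passed the threshold with a trend of variance on signal, and also without that trend when the fit was run on the 8271 bright genes alone. Whether any gene passed thus depended on how the variance was modelled and on the filter. The spread in this fit comes from the difference between the 2 control pools, which includes any effect of the non-targeting siRNA, and the lone siPIR pool is assumed to vary like them.

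By unadjusted limma p under 0.05, all 30 mitosis genes and 28 of 29 replication genes were lower, and the same 30 and 28 passed when adjusted over the list alone, against 0 for every list when adjusted over all genes. Where all members of a list have a p under 0.05, adjustment over that list alone passes all of them, so it adds nothing for the mitosis list. With the variance trend, members of most lists passed adjustment over all genes, some in each direction. The median total degrees of freedom were then 130, against 3.3 without the trend. Those calls rest almost wholly on a variance shared over genes, taken from the difference between the control pools. The counts that follow are from the fit without the trend. Adjusted over the list alone, limma also called 6 cholesterol genes lower (7 unadjusted), 4 senescence-associated regulators lower and 1 higher (6 and 1 unadjusted), 1 NF-kB target higher (8 higher and 1 lower unadjusted) and 1 fibroblast marker higher (2 unadjusted). The p53 list had 10 higher and 1 lower members at an unadjusted p under 0.05, the hypoxia list 7 higher, the interferon list 5 higher and 2 lower, the NRF2 list 3 higher and the migration list 3 higher and 1 lower. The MAPK list had 1 higher and 2 lower, the unfolded protein list 2 higher and 2 lower, the NFI and BCL3 and heat shock lists 1 higher and 1 lower each, the lysosome and leukocyte lists 1 higher each, and the pigmentation, keratinocyte and endothelial lists 0. In these lists 0 members passed limma when adjusted over the list alone.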

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

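The test on hybridisation controls was chosen after the spike difference had been seen. The test on the ratio between spike transcripts was set to explain that same difference, before its own result. Bacterial poly-A control transcripts (dap, lys, phe and thr), which are added to RNA before labelling and enter none of the comparisons, gave a signal in the siPIR pool above that in the siCTR pool by a median of 1.02 on the log2 scale over 24 probe sets. The NO pool was above siCTR by 1.30, so the siCTR pool stood apart, at -1.18 from the mean of the others (2.26-fold, from -1.54 to -0.99 over probe sets). The controls added at hybridisation (bioB, bioC, bioD and cre, 18 probe sets) differed by -0.11, which argues against a loss of signal at hybridisation or scanning of the siCTR arrays. The 4 poly-A transcripts moved by nearly the same factor, with medians 0.17 apart, which is what a lower amount of spike against RNA at labelling would give. These transcripts do not come from the cells, but their signal is relative to the RNA of the pool. No biological explanation was tested.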

How the results depend on the processing

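Over the alternatives, all of which were planned, 5108 values of named genes stayed the same within the spread of duplicate arrays, 335 moved and 2 called values reversed, RBFOX1 in siCTR against NO (-0.10 as the mean over probe sets) and CAPS in siPIR against siCTR (-1.28 without siPIR replicate 2, up to 3.08 without another array). Of those that moved, 50 changed sign, all of them values not called, most as the mean over probe sets or where another probe set came to represent the gene. These include CAPS in siPIR against NO and CDH11 in siPIR against siCTR (-2.65 and 1.98 without siPIR replicate 2). A change of sign within the spread was seen in 114 more. With an array left out, 23 of 104 dim and 8 of 90 bright called values fell below 2-fold or changed sign, and 23 dim and 1 bright moved by over 1.5 times. Of the list medians, 561 kept their side of the random range, 32 of them with a change of sign within it, 13 entered the called range, 26 left it and 3 reversed. The replication, mitosis, senescence and p53 medians against either control were among those kept under every alternative. Dim signals limit the calls, as 10.0% to 14.8% of dim genes but at most 0.073% of bright genes were at least 2-fold apart between duplicate arrays. Where no cause is given below, the cause was not tested.

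Counts are given as higher and lower. Without the filter, which adds dim genes, they were 1220 and 1170 (siPIR against siCTR), 1095 and 1437 (siPIR against NO), 414 and 650 (both controls) and 707 and 1028 (siCTR against NO). With the filter at the 75th percentile, which removes dim genes, they were 110 and 331, 177 and 353, 75 higher against both controls, and 2 and 3. At 1.5-fold they were 1388 and 1304, 1541 and 1661, 819 and 979, and 367 and 691, and at 3-fold 150 and 195, 140 and 231, 37 and 134, and 48 and 130. With 4 times the pseudocount siCTR against NO had 77 and 206. The limma fit on the 6 arrays, which sets these pools against hybridisation error only, gave 1472 and 1564 against siCTR, 1947 and 1809 against NO, and 0 and 0 for siCTR against NO. On 3 pools, limma gave 1034 and 1080 with the filter at the 75th percentile and 1381 and 1373 with the variance trend, against 0 otherwise. The trend shared 460 of its genes with the 610 called against both controls.

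With arrays paired by number (replicate block), the counts were 216 higher for siPIR against siCTR, 276 and 456 against NO, 95 higher against both controls, and 59 and 141 for siCTR against NO, since each same-numbered pair must then differ 2-fold. The numbers did not pair the arrays, whose deviations correlated at -0.0086, 0.024 and -0.0083, and the block moved no other count by over 1.5 times.

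Leaving out 1 array relaxes the rule, since a lone array cannot overlap its partner. It also leaves the noise of 1 array in the pool value and chooses probe sets and measured genes anew. These effects were not separated. Counts ranged over 569 to 784 and 625 to 982 against siCTR, and 536 to 691 and 758 to 963 against NO. They ranged over 194 to 358 and 434 to 553 against both, and 211 to 509 and 407 to 596 for siCTR against NO. Moves of over 1.5 times came without siPIR replicate 1 (784 higher against siCTR, 358 against both, 300 without siPIR replicate 2) and without siCTR replicate 2 (982 lower against siCTR, 509 and 505 for siCTR against NO). Without NO replicate 1, siCTR against NO had 246 and 596, without NO replicate 2 it had 211 and 491, and without siCTR replicate 1 it had 225 higher. The limma count stayed at 0.

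Among list medians of siPIR against NO, NRF2 was 0.23 at 4 times the pseudocount, 0.19 at the 75th percentile, 0.21 without _x_at and _s_at probe sets and 0.21 to 0.28 without single arrays; interferon was 0.25 without the filter and 0.25 to 0.36 without single arrays; and fibroblast was 0.42 without the filter and 0.34 to 0.94 without single arrays. Against siCTR, fibroblast was 0.92 without the filter and 0.22 to 0.67 without single arrays (0.67 without siPIR replicate 2), MAPK 0.23 at the 75th percentile, NRF2 0.22 and lysosome 0.19 as means over probe sets, and, without _x_at and _s_at probe sets, NF-kB 0.30 and migration 0.22. Migration was 0.14 to 0.18 without single arrays, called without siCTR replicate 1 alone.

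For siCTR against NO, lysosome was 0.10 at the 75th percentile, 0.069 without _x_at and _s_at probe sets and 0.092 to 0.13 without single arrays, and NFI and BCL3 partners -0.16 at the 75th percentile, 0.058 as means over probe sets and -0.30 to 0.042 without single arrays (reversed at 0.042 without NO replicate 1). Hypoxia became called at 0.093 with quantile normalisation, 0.12 as means over probe sets and 0.17 without _x_at and _s_at probe sets, and was 0.067 to 0.15 without single arrays (called without siCTR replicate 1 or NO replicate 2). As means over probe sets and without _x_at and _s_at probe sets, mitosis became called at 0.12 and 0.13, interferon was -0.11 and -0.11 (-0.19 to -0.11 without single arrays) and no longer called, and cholesterol -0.016 (reversed) and 0.14 (no longer called), and pigmentation became called at -0.081, with its sign turned, as means over probe sets.

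PIR differed from siCTR by -5.03 and from NO by -5.11 at 4 times the pseudocount, and from NO by -5.21 with quantile normalisation. Between siCTR and NO it differed by -0.12 with quantile normalisation and -0.018 with median centring. PIR has no value without _s_at probe sets, as its measured probe set is of that kind.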

Other observations

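The histone and protocadherin lists, and the tests of any siRNA, scaling and other siRNA targets below, were chosen after the values were seen, while the tests of dim-gene noise were set before their result. Protocadherin beta genes, a cluster of neighbouring cell adhesion genes, were read because some had been seen among the higher genes. Of 15 measured members, 14 of them bright, 15 had a positive difference from siCTR and 13 from NO, with medians of 0.79 and 0.82, against 0.05 between siCTR and NO. A rank among random lists is not given, as the list was chosen for this direction. PCDHB14 (1.46 and 1.52), PCDHB18P (1.20 and 1.26), PCDHB3 (1.05 and 1.20) and PCDHB11 (1.05 and 1.03) were called higher than both controls. Members are similar in sequence and the last 3 rest on probe sets that can bind several genes, so they are not separate measurements.

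Histone genes lay on both sides. Of 21 measured genes of the histone clusters, H2AC6, H2BC21, H2BC12 (1.15 and 1.02) and H3C6 (1.16 and 1.90, dim) were higher than both controls, while H3C3 (-2.31 and -2.07) and H2BC14 (-1.17 and -1.36), both dim, were lower, with list medians of 0.29 and 0.04. The 8 measured histone genes outside the clusters had medians of -0.50 and -0.36, and CENPA, the centromeric histone, was lower (-1.58 and -1.38, uncertain probe set). The difference between these lists was not tested.

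Among the gene lists, the lower replication and mitosis genes in the siPIR pool are the broadest pattern. Of the 281 bright genes lower than both controls, 48 are in these lists and 233 in neither. The replication list holds 27 bright genes and the mitosis list 29, so most of the 281 could not be members. Those outside were not sorted by function, and they include DEPDC1 and NCAPH, described above as mitotic or condensin genes. An effect of any siRNA would lower the members of both lists in siCTR as well, but their median there was 0.08 above NO. Array scaling would shift all genes alike, but their median lay at -1.66 from that of all measured genes for siPIR minus siCTR. Targets of the PIR duplexes other than PIR stay open and cannot be told apart from the loss of PIR, as the design holds 1 pool of duplexes and no single duplex or re-expression. Any other difference between the siPIR cultures and the control cultures is confounded in the same way, as each group is 1 RNA pool. Slower division after loss of PIR is therefore a hypothesis only, for which cell counts or DNA content with each single duplex and after re-expression of PIR would be the test.

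Calls among dim genes are the other pattern. Between the control pools, 438 dim genes were called, and simulated pools without any difference gave a median of 248.5 (at most 289), while 12.2% of dim genes were at least 2-fold apart between duplicate arrays on average. Hybridisation noise may therefore account for many of these calls, and what the rest are stays open. Of the 117 dim genes higher than both controls in the siPIR pool, noise gave 34 (at most 46), so noise may explain part of them, and these values do not settle which. The same holds for the 137 dim genes lower than both controls, where noise gave 34 (at most 48).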
